A study of Homo sapiens with 4 samples.

How the data were processed

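Human umbilical vein endothelial cells were treated with TNF at 100 U/mL or with vehicle for 2 h, and monosome and polysome fractions were collected from sucrose gradients, per the labels. RNA of each fraction was reverse transcribed from oligo dT primers with a radioactive nucleotide and hybridised to 4 identical GF 211 nylon filters of spotted human cDNA, which were read by phosphorimager with the Pathways 3 software, per the series' design text. Each of the 4 groups (control monosome, control polysome, TNF monosome, TNF polysome) was 1 sample on 1 filter. The control monosome sample was placed by its title, which calls it a control but also names TNF, and its source name mentions both TNF and vehicle. Every ratio computed from this filter rests on that reading, namely TNF over control on monosomes, the mean of both fractions, polysome over monosome in control cells and the index. Only TNF over control on polysomes and polysome over monosome in TNF-treated cells leave it out.

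The deposited table gives spot intensity on a linear scale, normalised by the authors, for 4132 elements and 4 samples, with no value at or below 0. Per the design text, each signal was divided by the average signal of its filter, and elements counted as above background when signal over background exceeded 1.1. The deposited values are instead scaled to the median, since every filter has a median of 1, with means of 4.09 (control monosome), 4.17 (control polysome), 4.24 (TNF monosome) and 4.09 (TNF polysome). Which rows the authors removed, whether background was subtracted, and the background level of each filter are not given in the sources used here. No signal over background can therefore be stated, and the 5th percentile of each filter lay at 0.333 to 0.396 of its median. The low number of arrays limits precision, and no spread between cultures was measured.

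Each value was divided by its filter's mean, following the design text, and taken to log2 with no offset. The quantities computed were TNF over control on polysomes and on monosomes, the mean of these log2 ratios, polysome over monosome (the translation state) in control and in TNF-treated cells, and the translation index, which is the translation state with TNF over that in control cells. The limits of 2.5 and 0.4 are those of the design text for the index and were used for all ratios. Elements with a mean log2 value over the 4 filters at or above the median of all elements, 0.242 times the filter mean, are called the brighter ones (2066 elements). With 1 filter per group no conditions were tested against each other, and neither p-values across genes nor SDs of conditions were computed.

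Gene symbols came from a table of the platform's annotation, which can be old. Of the elements, 1582 had exactly 1 symbol, 52 had several and were not named, and 2498 had none in the table; element numbers are given for unnamed ones. Gene IDs of 1580 of the single-symbol elements matched the RefSeq gene table. Several elements of a gene were averaged on the log2 scale (36 genes, 86 elements). Genes of the Y chromosome and XIST were left out. No coordinates are given, since no build is named for the array.

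Named genes followed a rule set before the data were examined. It took the 12 highest and 12 lowest genes of the brighter elements past the limits for the index and for TNF in each fraction, fewer where fewer passed, and the 6 highest and 6 lowest for polysome over monosome in control cells. Members of the fixed lists were added, namely those of the first 3 lists (TNF and NF-kB early targets, adhesion molecules, chemokines and cytokines) past 2 or 0.5 in either fraction, and from other lists the 2 highest and 2 lowest members. That last part was set without naming a contrast and was not followed for every list; members at both ends are given for lists with a percentile, in a contrast the text describes. Other list members appear as examples chosen after their values were seen, as do TRIP13, GRIA2, MRPL3 and genes named only in the closing section. The 26 lists held 801 genes, of which 138 had a value, and 13 lists had the 5 measured genes needed for a percentile. The result of 1 of these lists is not reported here, although it is included in the numbers of lists and pairs. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean log2 value in 10 bins. Repeatability was described by the SD between elements of 1 gene. In a permutation test these elements were replaced by random draws from all elements with 1 symbol, matched on brightness in 10 bins. The draws were not limited to genes with several elements.

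Alternatives set before the data were examined were division by the filter median, quantile normalisation, removal of the lowess trend (fraction 0.3) of the ratio on brightness, addition of each filter's 10th percentile before scaling, limits of 2 and 0.5, elements at or above the 75th percentile of brightness or all elements in place of the brighter ones, a stand-in for background of 1.1 times the 5th percentile, and the brightest element in place of the average of a gene.

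The calculations were tested on simulated data, 4132 elements in which 200 were made 4-fold higher on the TNF polysome filter with noise of 0.244 (SD, log2) per filter. Mean scaling placed 83% of them above 2.5 and median scaling 89.5%, while 50 and 27 unchanged elements passed a limit. The noise was set so that it alone gives the index its observed SD of 0.487, equal at every brightness. All of the observed spread is thus treated as noise. In the data 50 elements passed an index limit, so their number alone does not separate change from noise. The bar for recovery was first set above the value that mean scaling reached and was lowered once it was seen. By construction the changed elements also raise the mean of their filter, by which they are then divided. A list of 20 genes made higher by 0.5 (log2) reached the 100th percentile and an unaltered list the 78.2nd. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.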

Results

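Messenger RNA bound to ribosomes was compared between resting and stimulated human umbilical vein endothelial cells, the primary cells that line that vessel. The cells had received tumour necrosis factor alpha (TNF), an inflammatory cytokine, at 100 U/mL for 2 h, or vehicle alone. Lysates were separated on sucrose gradients into a monosome fraction, where a message carries a single ribosome, and a polysome fraction, where it carries several. Radiolabelled cDNA from each fraction was hybridised to its own copy of 1 nylon cDNA filter type. There were 4 groups with 1 filter each, namely control monosome, control polysome, TNF monosome and TNF polysome, so none of the differences has a replicate check, and every ratio describes these 4 filters. Each filter held values for 4132 array elements, of which 1582 carried exactly 1 gene symbol, covering 1530 genes. The 100 brightest elements held 50.0% of the summed intensity on the control monosome filter, 52.2% on the control polysome filter, 52.2% on the TNF monosome filter and 48.9% on the TNF polysome filter. Across elements, which are not independent replicates, log2 intensities of filter pairs correlated with r between 0.940 and 0.975. Levels are given as multiples of the filter mean, and counts refer to the 2066 elements at or above the median brightness, called the brighter elements, unless stated otherwise.

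The first question was which messages differed in abundance with TNF within each ribosomal fraction. CX3CL1, the membrane-bound chemokine fractalkine, was 7.87-fold higher with TNF on polysomes and 7.09-fold higher on monosomes, from 0.217 to 1.71 and from 0.223 to 1.58 times the filter mean. UBD, a ubiquitin-like protein modifier, was 6.56-fold higher on polysomes, from 0.111 to 0.729 times the filter mean. On monosomes it was 2.88-fold higher, from 0.139 to 0.401. TRAF1 and TANK, adaptor proteins of TNF receptor signalling, were 4.63-fold and 3.08-fold higher on polysomes, and 2.02-fold and 2.61-fold higher on monosomes. RCAN1, an inhibitor of calcineurin, was 2.98-fold higher on polysomes and 2.09-fold higher on monosomes. CX3CL1, UBD, TRAF1 and RCAN1 were below 0.242 times the filter mean, the limit of the brighter elements, on both control filters. They passed that limit through their TNF filters. SOD2, the mitochondrial superoxide dismutase, went from 2.15 to 6.17 times the filter mean on polysomes, a ratio of 2.88, and from 1.73 to 3.61 on monosomes, a ratio of 2.09.

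Named genes below the lower limit were 1 on polysomes and 4 on monosomes, and each passed it in 1 fraction only. GPM6B, a membrane glycoprotein, had a polysome ratio of 0.387 beside a monosome ratio of 1.14. On monosomes the ratio was 0.312 for SYNPO, an actin-associated protein, 0.359 for MPPED2, 0.387 for DPF2 and 0.387 for ACADSB, an acyl-CoA dehydrogenase. The polysome ratios of these 4 genes were 0.978, 0.949, 0.903 and 0.748. COL6A2, a chain of collagen VI, was the 1 element of the array whose mean log2 TNF ratio over both fractions lay below a ratio of 0.5. It stood at 0.50 on polysomes and 0.470 on monosomes.

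**Figure D1:**
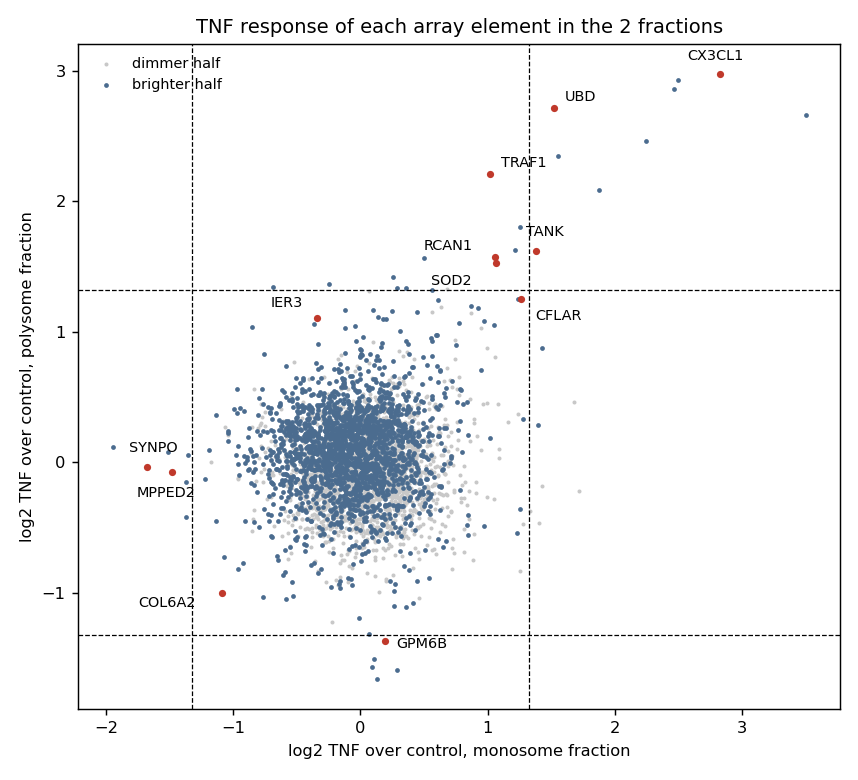
Each point is an array element, with its log2 ratio of TNF over control intensity in the monosome fraction on the horizontal axis and in the polysome fraction on the vertical axis. Dashed lines mark ratios of 2.5 and 0.4, blue and grey points are the brighter and the dimmer elements, and red points are named genes. CX3CL1, UBD and TANK lie beyond the upper limit in both fractions, and no element lies below the lower limit in both.

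Among the brighter elements, 20 were above a TNF ratio of 2.5 and 5 below 0.4 on polysomes, and 11 were above and 7 below on monosomes. Of all 4132 elements, 9 were above 2.5 in both fractions, against 0.0813 if the fractions were independent, and 0 were below 0.4 in both. CX3CL1, UBD and TANK were the 3 of these 9 with a symbol. Among the 6 without one, element 2644 was 6.33-fold higher on polysomes and 11.3-fold higher on monosomes, and element 2543 was 7.63-fold and 5.66-fold higher. The TNF ratios of polysomes and monosomes had a Pearson r of 0.136 and a Spearman correlation of 0.0035 across all elements, and 0.261 and 0.0728 across the brighter ones. Other scalings moved the monosome split to 12 above and 4 below with median scaling, 14 and 4 with quantile normalisation, and 13 and 4 with the lowess trend removed. Adding the 10th percentile of each filter to its values brought RCAN1 and GPM6B on polysomes, and UBD, TANK, MPPED2, DPF2 and ACADSB on monosomes, back inside the limits. DPF2 and ACADSB, close to the limit at -1.37 each on the log2 scale, also came back inside with median scaling (-1.32 for each), quantile normalisation (-1.28 and -1.27) or the lowess trend removed (-1.31 and -1.28).

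Known early targets of TNF and NF-kB had higher values in both fractions as a group. The list of 37 genes had 11 with a value, of which 10 had a monosome ratio above 1 and 7 a polysome ratio above 1. Its median ratio was 1.51 on monosomes, above every one of 10000 random lists matched on brightness, and 1.34 on polysomes, at the 99.96th percentile. Over its 7 brighter members the polysome median was 1.11 on the log2 scale, against 0.42 over all 11. Brighter members are chosen partly on the TNF filters, which favours genes higher with TNF. Those left out were GCH1, IL15 and IL15RA, each below 1 on polysomes, and IRF1, above 1. CFLAR, an inhibitor of death-receptor apoptosis, stood at 2.39 on polysomes and 2.40 on monosomes, and the transcription factor IRF1, a dim element, at 2.28 and 1.55. BMP2 stood at 1.16 and 1.11 and NINJ1 at 1.34 and 1.51. The lowest polysome ratio was that of CD83, 0.750, beside 1.30 on monosomes. The cytokine IL15, its receptor chain IL15RA and GCH1, all dim elements, had polysome ratios of 0.813, 0.792 and 0.900, beside monosome ratios of 1.21, 1.03 and 1.61.

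Immediate early genes, which respond to many stimuli without new protein synthesis, also had higher values. The median over 12 measured genes was 1.25 on polysomes (99.3rd percentile) and 1.16 on monosomes (99.1st percentile). DUSP6, a phosphatase of ERK, stood at 1.76 and 1.48, EGR3 at 1.71 and 1.19, KLF6 at 1.66 and 1.14, and JUNB at 1.54 and 1.65, whereas IER2 stood at 0.969 and 1.10 and SGK1 at 0.963 and 0.848. Interferon response genes had a median of 1.31 on polysomes (6 genes, 99.8th percentile) and 1.11 on monosomes (82.6th percentile), with the exonuclease ISG20 at 2.51 and 1.60, IFIT2 at 1.57 and 1.71, IRF2 at 1.08 and 0.980 and SP110 at 0.852 and 0.975, all dim elements. Apoptosis regulators had a polysome median of 1.27 (7 genes, 99.4th percentile), beside a monosome median of 0.918 (19.6th percentile). Their polysome ratios were highest for BNIP2, a dim element, at 1.42 and CASP10 at 1.36, and lowest for CASP9, a dim element, at 0.888 and CASP4 at 0.924. Components of NF-kB and TNF receptor signalling had a monosome median of 1.29 (9 genes, 99.6th percentile), a polysome median of 1.06 (71.5th percentile) and a median index of 0.924 (23.4th percentile). TANK, TRAF4 and TNFRSF10B were the members with the highest monosome ratios, 2.61, 1.55 and 1.53, and TRAF4 and TNFRSF10B were dim elements, while TRAF5 and TAB1 had the lowest, 0.679 and 0.754. Proteasome subunits had a polysome median of 1.32 (6 genes, 99.1st percentile) and a monosome median of 1.10 (86.2nd percentile), with polysome ratios from 1.78 for PSMC6 and 1.51 for PSME1 to 0.977 for PSMB10, a dim element, and 0.860 for PSMA1. MAP kinases and stress kinases had a polysome median of 0.879 (9 genes, 4.04th percentile), with MAP2K4 at 0.697 and MAP2K6 at 0.772 lowest and MAPKAPK2 at 1.10 and MAPK8 at 1.05 highest, where MAP2K6 and MAPK8 were dim elements.

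**Figure D2:**
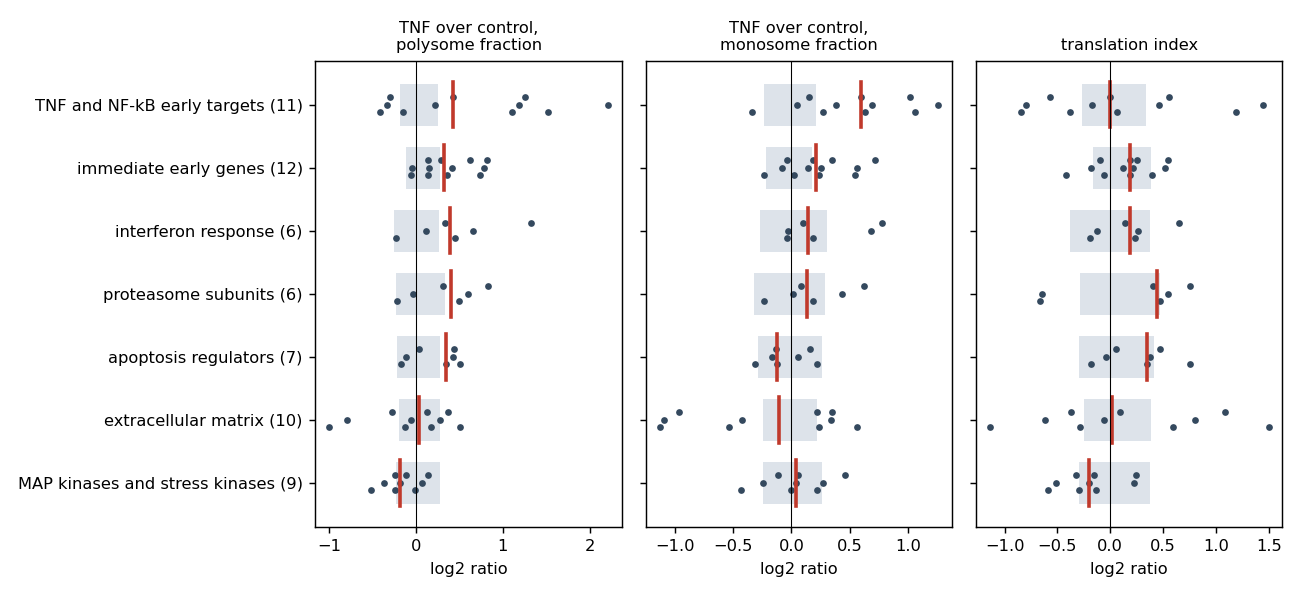
Log2 ratios of the measured members (points) of 7 fixed gene lists for TNF over control on polysomes, on monosomes, and for the translation index, with the number of measured genes beside each name. Red bars are list medians, and grey bands hold the central 95% of medians of 10000 random lists matched on brightness. The median of the TNF and NF-kB early targets lies beyond the band in both fractions and within it for the index.

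Chemokines, cytokines and adhesion molecules had fewer than 5 measured genes each, so no percentile was computed. Besides CX3CL1, the interferon-inducible chemokine CXCL10 stood at 1.19 on polysomes and 0.616 on monosomes. TNFSF10 and VEGFA, both dim elements, stood at 1.04 and 1.00 and at 0.851 and 0.805. VEGFA lay between 0.0575 and 0.0772 times the filter mean on the 4 filters. The endothelial cadherin CDH5 stood at 1.09 and 1.37, the integrin chain ITGAV at 0.981 and 1.27, and ALCAM, a dim element, at 1.05 and 0.935. Endothelial markers had a median of 1.09 on polysomes (66.7th percentile) and 0.829 on monosomes (4.29th percentile) over 5 genes, with ANGPT2 at 1.49 and 0.701, EPHB4 at 1.15 and 1.07, KDR, a dim element, at 0.809 and 0.829, and ECE1 at 0.796 and 1.23. Smooth muscle and fibroblast markers had medians of 1.01 on polysomes (55.2nd percentile) and 1.08 on monosomes (73.1st percentile) over 6 genes, with FAP, a dim element, at 1.17 and 1.36, THY1 at 1.15 and 1.06, CALD1 at 0.922 and 1.08, and CNN1 at 0.729 and 0.879. Of the leukocyte markers, CD79B, a dim element, stood at 2.22 and 1.47 and CSF1R at 0.533 and 1.17, and no epithelial marker on the list had a value.

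The translation index asked whether TNF moved a message between monosomes and polysomes. The polysome over monosome ratio in TNF-treated cells was divided by that in control cells, so a value above 1 means relatively more of the message on polysomes with TNF. IER3, an early response gene and NF-kB target, had an index of 2.72, with 0.996 on monosomes and 0.546 on polysomes in control cells, and 0.788 and 1.18 in TNF-treated cells. KSR1, a scaffold of the MAP kinase pathway, had an index of 2.50. SYNPO, MPPED2 and COL6A1, another chain of collagen VI, had indices of 3.13, 2.64 and 2.82, and in these genes the control monosome value was above the other 3. It was 1.84 for SYNPO against 0.430, 0.575 and 0.420, and 0.412 for COL6A1 against 0.199, 0.188 and 0.256, on control polysomes, TNF monosomes and TNF polysomes. GPM6B had an index of 0.339 and BLZF1, a Golgi protein, 0.363. These 7 were all the genes of the brighter elements past 2.5 or 0.4 by the average of their elements.

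**Figure D3:**
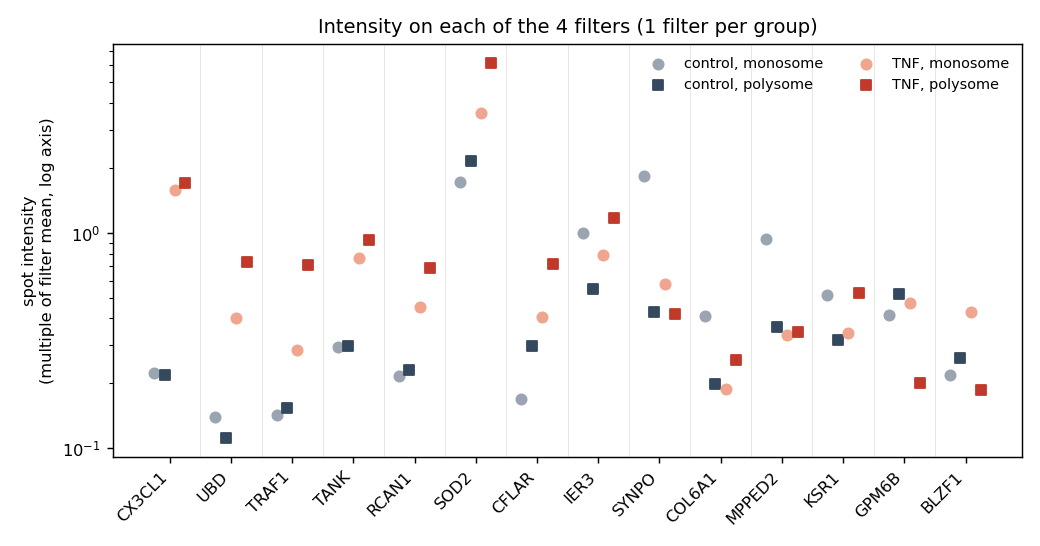
Spot intensity of 14 genes on each of the 4 filters, as a multiple of the filter mean on a log axis. Grey and dark blue are control monosomes and polysomes, light and dark red TNF monosomes and polysomes, with 1 filter per group and so no error bars. CX3CL1, TANK and SOD2 are higher on both TNF filters, whereas SYNPO and MPPED2 stand apart on the control monosome filter.

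In all, 20 of 4132 elements had an index above 2.5 and 30 below 0.4, and among the brighter elements 18 were above and 15 below. The brighter elements had a median index of 1.13 and the dimmer ones of 0.937, and the split depended on the scaling. It was 13 above and 20 below with median scaling, 7 and 23 with quantile normalisation, and 9 and 26 with the lowess trend on brightness removed; over all elements it became 13 and 40 with median scaling. The index of IER3, MPPED2 and KSR1 fell inside the limits with quantile normalisation or the lowess trend removed, and that of MPPED2 and KSR1 also with median scaling. Only SYNPO, of the 7 genes, remained past its limit when the 10th percentile of each filter was added to its values.

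Among genes with higher values in both fractions, the index was 1.11 for CX3CL1, 1.18 for TANK, 0.995 for CFLAR, 1.37 for SOD2, 2.28 for UBD and 2.29 for TRAF1. The indices of UBD and TRAF1 rest on dim control values, 0.111 to 0.153 times the filter mean. The TNF and NF-kB early targets had a median index of 0.995 (39.3rd percentile), which moved to -0.19 on the log2 scale with quantile normalisation; GCH1 and CD83 had the lowest, 0.557 and 0.575. Among matrix genes the index ranged from 2.82 for COL6A1 and 2.13 for LAMA4, which was likewise highest on the control monosome filter (0.601 against 0.264, 0.308 and 0.288), to 0.654 for NID1 and 0.454 for the membrane protease MMP14, around a median of 1.01 (10 genes, 36.9th percentile). ANGPT2, a ligand of the endothelial receptor TIE2, had an index of 2.13. Proteasome subunits had a median index of 1.36 (6 genes, 96.5th percentile), which on the log2 scale was 0.44, and 0.25 (81.6th percentile) with the brightest element of each gene. PSMC6 and PSMD3 had the highest, 1.69 and 1.46, and PSMB10 and PSMA1 the lowest, 0.632 and 0.638. PSMA1 and NID1 were among the 100 brightest elements of the array, which had a median index of 0.841. Apoptosis regulators had a median index of 1.27 (95.7th percentile), with CASP10 at 1.68 and, as dim elements, BAK1 at 1.39, CASP9 at 0.974 and DAPK1 at 0.880. Translation initiation factors had a median index of 1.16 (5 genes, 68.4th percentile), with EIF4G1 at 1.23, MKNK1 at 1.20, EIF1 at 1.14 and EIF2B5, a dim element, at 1.01.

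Different elements of 1 gene give the single repeat measurement within a filter. Over 36 genes with 86 elements, the SD of the log2 index between elements of a gene was 0.530. Brightness-matched elements drawn at random from all elements with 1 symbol gave a median of 0.481 (1-sided permutation p = 0.832). The 86 elements themselves had an SD of 0.562 regardless of gene, against 0.487 over all elements of the array. The draw does not hold the spread of these elements fixed, so it cannot tell whether elements of a gene lay closer together than others. Elements of 1 sequence accession differed in brightness by a median of 1.80 on the log2 scale, and over the 22 brighter elements of 10 genes the SD within genes was 0.458, against 0.573 over these elements regardless of gene. For the mean TNF ratio of both fractions the SD was 0.216 between elements of a gene and 0.244 over the 86 elements. Random draws of the same kind gave 0.266 (1-sided permutation p = 0.0681). TRIP13 had 1 element with an index of 3.71 and another with 0.917, and GRIA2 had 1 with 3.02 and others with 0.664 and 0.612. The MRPL3 elements, by contrast, all lay above 1, at 2.90, 1.58 and 1.23.

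**Figure D4:**
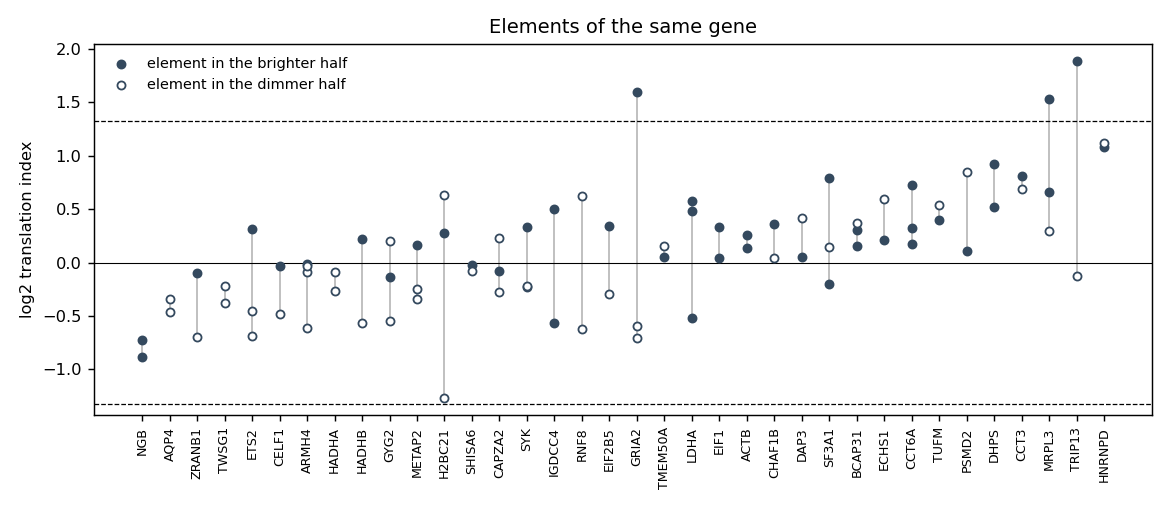
Log2 translation index of each element of the 36 genes with several elements, ordered by gene mean. Filled points are brighter elements, open points dimmer ones, grey lines join elements of a gene, and dashed lines mark an index of 2.5 and 0.4. TRIP13 and GRIA2 each have 1 element above the upper limit and other elements below an index of 1.

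The last comparison was of polysomes with monosomes within each condition. Each filter was divided by its own mean, so a ratio of 1 does not mean equal amounts of a message in both fractions. Monosome-heavy and toward polysomes are meant relative to these means. CYCS, cytochrome c, was the 1 named gene above 2.5 in control cells, with a polysome over monosome ratio of 3.47, and 2.50 in TNF-treated cells. SMARCD2, a subunit of a chromatin remodelling complex, was monosome-heavy in both, at 0.193 and 0.166, while SYNPO stood at 0.233 in control and 0.730 in TNF-treated cells. The selenoprotein SELENOW stood at 0.215 and 0.457, the ribosomal protein RPL31 at 0.270 and 0.438, the hypoxia-responsive transcription factor EPAS1 at 0.276 and 0.506, and ZNF200 at 0.318 and 0.381. Messages of the TOP class, whose 5' ends make them responsive to growth signals, were measured for 3 listed genes besides RPL31, too few for a percentile. BTF3 stood at 0.526 and 0.912, PABPC4 at 0.366 and 0.625, and NAP1L1 at 0.479 and 0.484.

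Proteasome subunits lay toward polysomes, with a median ratio of 1.59 in control cells (99.98th percentile) and 1.70 in TNF-treated cells (99.94th percentile) and all 6 measured genes above 1 in both. PSME1 stood at 1.72 and 2.28 and PSMD3 at 1.49 and 2.17, whereas PSMA1 stood at 1.70 and 1.08 and PSMB10, a dim element, at 1.77 and 1.12. PSMA1 was among the 100 brightest elements, whose median ratios were 1.31 and 1.00. Cell cycle and DNA replication genes had a median of 1.03 in control cells (47.1st percentile) and 1.19 in TNF-treated cells (98.5th percentile), with CDK1 at 0.954 and 1.62 and AURKA at 1.70 and 1.24, both dim elements, CDKN1B at 0.948 and 1.42, CDK6 at 0.766 and 0.760, and MKI67, a dim element, at 1.03 and 0.819. Their median index was 0.993 (59.5th percentile). Endothelial markers had a median of 0.746 in control cells (4.09th percentile) and 1.00 in TNF-treated cells (44.2nd percentile), with ECE1 at 1.54 and 1.00, KDR, a dim element, at 0.804 and 0.785, EPHB4 at 0.680 and 0.726, and ANGPT2 at 0.676 and 1.44. Their median index was 1.07 (60.6th percentile).

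In control cells 22 brighter elements had a polysome over monosome ratio above 2.5 and 77 below 0.4. In TNF-treated cells 55 were above and 30 below, or 42 and 36 with quantile normalisation and 40 and 37 with the lowess trend removed. The ratios of both conditions had a Pearson r of 0.532 across all elements and 0.677 across the brighter ones. Over all elements and on a common scale, the contrast between fractions had an SD of 0.882 (log2), that between treatments 0.559 and their interaction, the index, 0.487. The scaled median absolute deviation, which outliers move less, was 0.688, 0.450 and 0.465 in the same order. Among the brighter elements the SDs were 1.10, 0.635 and 0.486. In all, 78 pairs of list and contrast were given a percentile, and 16 lay outside the central 95%, where about 3.9 would by chance. The ratios of a list share the same 4 filters, so these 16 are not separate results and their excess cannot be judged. Percentiles describe these 4 filters and are not p-values.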

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

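The tests in this part were chosen after the results were seen, except that of a brightness trend behind the elements higher in both fractions, which was set before. For 5 of the genes past an index limit the TNF ratio lay above 1 in one fraction and below 1 in the other, and these differences were not tested, since each group is 1 filter. On the log2 scale the index was 1.50 for COL6A1, 1.44 for IER3, 1.32 for KSR1, -1.56 for GPM6B and -1.46 for BLZF1.

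Among the brighter elements 33 passed an index limit, 8 above and 3 below with a symbol, and for those without one it is not known whether another spot of the same gene exists. Noise of single spots cannot be told apart from a message-specific difference here, because the other elements of the called genes, signed by the direction of the call, had a median index of -0.12 (log2) but covered 3 genes, and 4 of these 5 elements were dim while the brighter one, of MRPL3, stood at 0.66 in the direction of its call. Of the 33 calls, 11 (33.3%, exact 95% interval 18.0 to 51.8) traced to the control monosome filter, an interval that holds the 25% of 4 equal filters. Whether that filter stands apart cannot be told from all calls together. A control monosome value that is too high can only raise the index, so the high calls bear on it most. Among the calls above 2.5 the share was 9 of 18 (50%, 26.0 to 74.0), as for SYNPO, an interval above 25%. Over all elements it was 11 of 20 (55%, 31.5 to 76.9). Below 0.4 the share was 2 of 15, and 7 of 30 over all elements. The test was widened from the high calls to all calls after these values were seen. On the high calls alone the values go with this filter standing apart. A biological effect of TNF on translation stays open and untested.

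The 9 elements above 2.5 with TNF in both fractions, among them CX3CL1, UBD and TANK, rest on filters that the fractions do not share. If passing the limit were independent between fractions, 0.0813 elements would be there, with an upper 95% Poisson limit of 1, so noise of single spots is argued against by the count of 9. A brightness trend between filters is argued against as well, since all 9 stayed above 2.5 in both fractions once the lowess trend was removed. A candidate explanation is higher message abundance after TNF, but dishes treated alike were not repeated, so a difference between the control and the TNF dishes other than TNF stays open.

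Monosome-heavy messages such as RPL31, EPAS1 and SELENOW tended to have an index above 1, though SMARCD2 and TMED2 stood at 0.860 and 0.778. Among 91 brighter elements with a mean polysome over monosome ratio under 0.5, the median index was 0.47 on the log2 scale and 77 lay above 1, against 0.05 to 0.30 for random sets matched on brightness, and 78 elements with a ratio over 2 had a median of 0.31, with 61 above 1, against 0.08 to 0.32. A brightness trend is argued against as the whole cause, since 0.33 remained with the lowess trend removed. Regression to the mean could not be excluded, because elements chosen on the TNF filters, whose noise pulls the index the other way, had a median of 0.14, within the 0.04 to 0.31 of random sets, and those chosen on the control filters 0.60. This criterion was made stricter after choosing on the mean of both conditions had come out above the random sets, because a noisier control monosome filter would produce that too.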

How the results depend on the processing

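No paired analysis was possible because each group is 1 filter, so no replicates can be paired; an additive fit of treatment and fraction, whose single residual degree of freedom is the index itself, was not run. All alternatives were set before the data were examined, and no sign was turned among the 28 values of named genes past a limit. Of these, 24 stayed past it with median scaling, 23 with quantile normalisation, 23 with the lowess trend removed and 15 with the 10th percentile added. All 28 stayed with the brightest element per gene, but each of these genes has 1 element, so that setting could not change them. For the same reason it could not change the single-gene ratios, whose tally includes it. Of the counts and spreads 34 stayed within 1.5 times their value, which does not cover the splits by direction, and 14 moved, of list medians 405 stayed within 1 SD of random lists and 27 moved, and of single-gene ratios 378 stayed within the SD between elements of a gene and 7 moved. Adding the 10th percentile, which by construction shrinks ratios of dim elements, gave 13 elements past the index limits over all elements and 12 among the brighter ones, 53 for polysome over monosome in TNF-treated cells, 16 for TNF on polysomes and 9 on monosomes. Limits of 2 and 0.5, wider by construction, gave 169 and 100 for the index, 198 and 225 for polysome over monosome in control and TNF-treated cells, and 56 and 39 for TNF on polysomes and monosomes. Elements at or above the 75th percentile of brightness, fewer by construction, gave 20 for the index and 10 for TNF on monosomes, and all elements 50 for the index. The median of the TNF and NF-kB early targets (log2) was -0.19 for the index with quantile normalisation and -0.18 with the lowess trend removed. It was 0.43 on monosomes with the 10th percentile added, and on polysomes 0.29 with the lowess trend removed and 1.11 over the brighter elements. The brighter elements are chosen partly on the TNF filters, which favours genes higher with TNF. The cause of the other moves was not tested. The stand-in for background moved no count by over 1.5 times. Signal over background is not given, so its limit on dim elements is unknown.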

Other observations

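Relative to the filter means, several messages outside the lists lay toward polysomes in both conditions. PTMA, prothymosin alpha, had a polysome over monosome ratio of 2.14 in control and 3.59 in TNF-treated cells, VDAC3, a mitochondrial outer membrane channel, 2.38 and 2.97, NNMT, a nicotinamide methyltransferase, 2.14 and 2.77, and the splicing factor SRSF1 1.93 and 2.21. CADPS stood at 2.28 and 1.90 and was lower with TNF in both fractions, at 0.487 on polysomes and 0.587 on monosomes. On the monosome side, besides those already named, were NME4 at 0.363 and 0.389, the cyclin CCNG1 at 0.423 and 0.543, and PREPL at 0.387 and 0.488. WARS1, the tryptophanyl-tRNA synthetase, stood at 1.59 with TNF on polysomes and 1.20 on monosomes, while the synthetase YARS1 stood at 0.806 and 0.786.

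The 100 brightest elements had a median index of 0.841 and a median polysome over monosome ratio of 1.31 in control cells. Their 31 elements with 1 symbol included ACTB and CALD1, and also FANCG, SPIB, FCN1 and NGB. Of the 36 genes with several elements, 4 had every element past an index of 0.5 on the log2 scale in 1 direction. They were CCT3, DHPS and HNRNPD above 1 and NGB below 1. Brightness-matched elements drawn at random from all elements with 1 symbol gave a median of 1 and a central 95% of 0 to 3. The count was made after the values were seen.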
